A study of Mus musculus with 10 samples.

How the data were processed

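RNA from 10 samples of the NMC line, a normal mouse cholangiocyte line, was sequenced after 6 days in 3D double spheroids. There were 5 libraries from collagen I at 1 mg/mL and 5 from a laminin and collagen I mixture at 3:1 by volume. Per the labels' protocols, spheroids were released from the matrix on ice, RNA was column-purified with removal of genomic DNA, and stranded poly(A) mRNA libraries were made from 30 ng of RNA.

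The authors deposited one table of whole-number read counts per gene symbol, with a column for each library. Per the submitters' processing notes, the genome build was GRCm38 (mm10) and DESeq2 was used. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here. The counts carried no normalization, and each column matched the title of one library. The table held 18407 genes, of which 3984 had no count in any library. Totals ran from 4424725 to 8129979 counts per library, so that 3 counts, the limit that a count of 0 allows, corresponded to 0.369 to 0.678 CPM, the count scaled to a common library size. Such limits cover counting error only.

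Genes were kept with the default filterByExpr rule, which left 10789. Libraries were scaled with TMM factors, and the groups were compared with edgeR 4.0.16 (quasi-likelihood fit and F test, group as the only term, two-sided) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are laminin-rich matrix minus collagen I. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD. The series description calls the samples biological replicates but does not say how the cultures were divided, so p-values measure the spread between these samples. Every library comes from the same cell line.

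Gene lists were fixed before the data were examined. They held 1405 entries in 42 lists, and 1326 entries had a symbol in the table. The 36 lists with 5 or more tested members were compared with camera (limma 3.58.1, preset inter-gene correlation 0.01) on log2 CPM with a prior count of 2, and adjusted over the lists. Calls were also counted per list with the edgeR p adjusted over the list alone. The mitochondrially encoded and replication-dependent histone lists had no tested member and were not analysed here. Per-library list means and summed marker CPM were compared by two-sided exact permutation tests over 252 assignments, for which the smallest p is 0.00794. Their p-values were adjusted by the Benjamini-Hochberg method over the 36 lists, the 6 marker sums or the 4 library measures.

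The genes named in the text were set by a rule written before the data were examined. It took up to 6 genes per direction with the largest fold change among those with adjusted p below 0.05, a mean CPM of at least 5, an official-style symbol and group ranges of log2 CPM that did not overlap. It also took 12 genes whatever their values, and up to 3 called members of each list that passed or held 3 or more called genes, which added none. Genes named as list examples, and the called genes outside the rule, were chosen after their values were seen. The values of a few genes are not reported here.

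Gene positions, transcript lengths (longest transcript) and GC content came from GENCODE M21 on GRCm38, matched by symbol for 18338 of 18407 genes and 99.9% of those tested. Genes whose exons overlap a gene on the opposite strand are named as such in the report, because the strand setting of the counting is not stated.

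The alternatives set beforehand were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library size only, no filter, a filter of 1 CPM in 5 libraries, the replicate number as a block, a mean per library code letter, each library left out, a test against a fold of 1.5, 1 surrogate variable (sva 3.50.0), camera with an estimated correlation, and fry. After seeing the data, 4 kinds were added. Each library was left out for the calls adjusted over a list alone, and for genes named from the fit with the offset below. The libraries of code letter D or B were left out. The scalings and filters were also applied to the lists. A per-library spline trend (5 degrees of freedom each) of log2 CPM deviations on transcript length and GC content was removed, through an edgeR offset or before camera. That trend is fitted without regard to matrix, so it also removes any matrix effect that follows length or GC content.

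The steps were tested on simulated counts for the 10789 genes with 200 changed genes. Without library trends, the edgeR test recovered 71.6% of genes changed 1.5-fold. With the measured library trends kept in the simulation, the edgeR test recovered 23.9% of genes changed 1.5-fold, 74.6% at 2-fold and 100% at 3-fold, and 3 of its 135 calls were unchanged genes. The length and GC offset recovered 56.7%, 92.5% and 100%, with 9 unchanged genes among 175 calls, and the surrogate variable 44.8%, 89.6% and 100%, with 18 among 174. The simulated trends came from the same spline that the offset removes, and the spread of each gene was estimated with that trend removed. No other difference between libraries was simulated. The recovery with the offset was thus favored by construction and may be lower in the measured data.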

Results

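Poly(A) mRNA was profiled in normal mouse cholangiocytes, the epithelial cells that line bile ducts, to compare the effect of the surrounding matrix. Cells of the NMC line were grown for 6 days as 3D double spheroids in collagen I (5 libraries) or in a laminin-rich matrix of laminin and collagen I at 3:1 (5 libraries). Laminin is a main protein of basement membranes, on which bile duct epithelium rests, while collagen I is a fibrillar protein of connective tissue. Total counts were 6379255 on average in collagen and 6024769 in laminin, a difference smaller than the spread between libraries (two-sided exact permutation p = 0.643, adjusted 0.857 over 4 library measures, n = 5 per group). The lowest total was 4424725 and the highest 8129979. The closest pair of libraries differed by more than sampling noise, so all 10 were used as separate samples.

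In the laminin-rich matrix, 15 genes rose and 1 gene fell relative to collagen I. Igfbp5, a secreted binding protein of insulin-like growth factors, rose 4.07-fold, from 18.1 ± 2.47 to 73.7 ± 37.2 CPM (SD, n = 5 per group). Atp1b1, a subunit of the sodium pump, rose 1.59-fold, from 364 ± 42.1 to 580 ± 16.6 CPM. Bst1, a cell-surface enzyme of NAD metabolism, fell to 0.426 of its level in collagen, from 67.0 ± 10.2 to 28.4 ± 10.2 CPM.

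The other genes that the naming rule took were Car2, Ctsh, Sipa1l2 and Sema4g, all higher in laminin. Car2, a cytosolic carbonic anhydrase, rose 2.72-fold to 11.7 ± 3.40 CPM, and Ctsh, a lysosomal cysteine protease, rose 2.30-fold to 70.4 ± 9.45 CPM. Sipa1l2 rose 2.26-fold to 26.4 ± 4.88 CPM. Sema4g, a membrane-bound semaphorin, rose 2.20-fold, from 109 ± 21.2 to 240 ± 27.6 CPM. On the log2 scale the changes were 2.03 (SE 0.29) for Igfbp5, 1.44 (SE 0.23) for Car2, 1.20 (SE 0.17) for Ctsh, 1.18 (SE 0.20) for Sipa1l2, 1.14 (SE 0.14) for Sema4g and -1.23 (SE 0.21) for Bst1. Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.0165 for Sema4g to 0.0487 for Sipa1l2.

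Other called genes fall outside the rule and are named after their values were seen. They included Atp1b1 (1.59-fold), Ace (2.05-fold), Tnxb (1.76-fold), Rtn4rl1 (1.68-fold), Neurl1b (1.59-fold), Slc12a7 (1.55-fold), Pcx (1.49-fold) and Boc (3.59-fold, at 4.55 ± 1.83 CPM in laminin). Ace encodes angiotensin-converting enzyme, Slc12a7 a potassium-chloride cotransporter, Pcx pyruvate carboxylase and Boc a co-receptor for hedgehog ligands. In GRCm38 coordinates, Igfbp5 lies on chromosome 1 from 72857932 to 72874884, Car2 on chromosome 3 from 14886273 to 14900770 and Ctsh on chromosome 9 from 90054152 to 90076089. Sipa1l2 lies on chromosome 8 from 125418063 to 125569808, Sema4g on chromosome 19 from 44989101 to 45003397 and Bst1 on chromosome 5 from 43818885 to 43843986. Exons of Bst1, Atp1b1, Ace and Tnxb overlap those of Fbxl5, Nme7, Gm11651 and Cyp21a2-ps on the opposite strand, so their values are uncertain to the extent that the counting ignored strand.

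**Figure D1:**
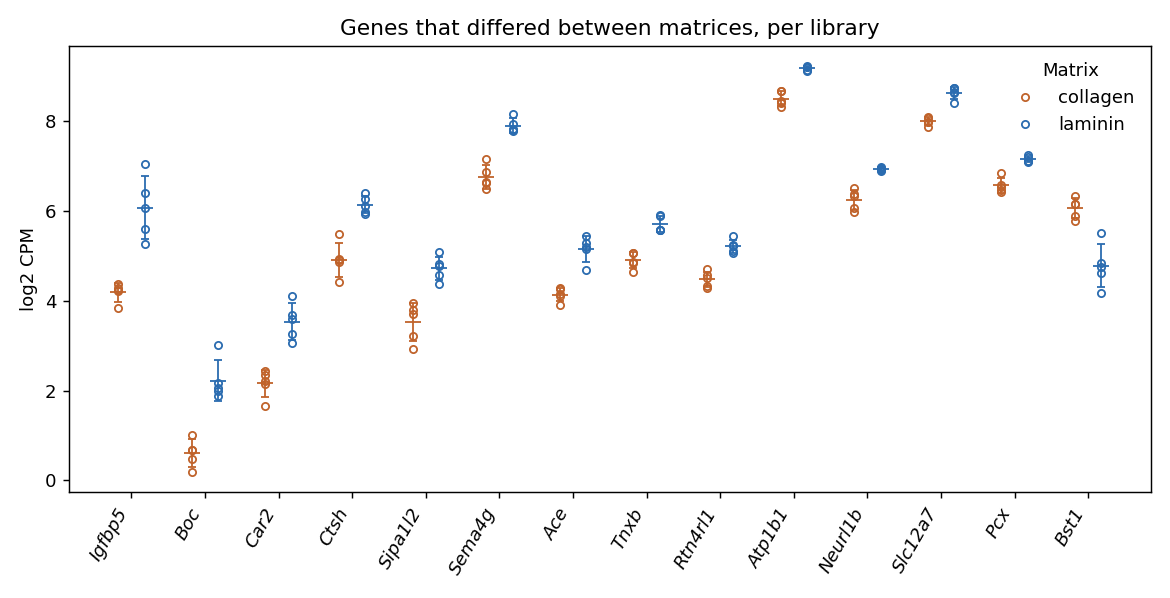
The y axis gives log2 CPM and the x axis 14 of the 16 genes that differed between matrices, with a circle for each library and bars for the mean and SD of 5 libraries per matrix. The circles of the matrices do not overlap for any of the 14 genes.

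All 16 genes had group ranges that did not overlap, as did 349 of the 10789 genes tested, or 3.23%, against 0.794% by chance. At an unadjusted p under 0.05 there were 1257 genes, and DESeq2 called 209. The number of edgeR calls was 0 without collagen replicate 3, collagen replicate 5 or laminin replicate 2 (1167, 939 and 977 at an unadjusted p under 0.05). It was 2 without collagen replicate 2, 5 without laminin replicate 3 or 5, 36 without laminin replicate 4 and 64 without laminin replicate 1. Each of the 16 genes kept its direction in all 23 alternatives. Since their group ranges did not overlap, this was nearly fixed beforehand and adds no support. With a fitted trend on transcript length and GC content removed, an alternative chosen after seeing the data, 122 genes were called, 89 higher and 33 lower, and Neurl1b and Tnxb no longer passed (adjusted p = 0.125 and 0.174 in edgeR).

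None of the 12 genes fixed beforehand passed the edgeR test with all libraries and no correction. Epithelial and biliary markers gave log2 differences of -0.13 (SE 0.23) for Krt19, 0.29 (SE 0.19) for Epcam, 0.11 (SE 0.18) for Sox9 and 0.42 (SE 0.19) for Cdh1. Krt7 was at 6.80 ± 3.98 CPM in collagen and 3.34 ± 1.62 CPM in laminin, and Vim, a mesenchymal intermediate filament, at 1698 ± 183 and 1343 ± 275 CPM. Of the matrix receptors, Itga6 gave -0.16 (SE 0.22), Itgb4 0.05 (SE 0.12), Itgb1 0.01 (SE 0.10), Itga2 -0.63 (SE 0.24) and Ddr1 0.16 (SE 0.12). Lama5, a laminin chain made by epithelium, gave 0.27 (SE 0.15). Their adjusted p ran from 0.335 for Itga2 to 0.979 for Itgb1. Itga2 passed with 1 surrogate variable (adjusted p = 0.0302) and with the length and GC offset (0.0393), in a range over the alternatives of 0.0302 to 1.00. Without collagen replicate 2, which stood at 53.7 CPM against 19.5 to 32.3 CPM in the other collagen libraries, Itga2 gave -0.36 uncorrected and did not pass with the offset (adjusted p = 0.0879). With the offset, Itga2 passed in 4 of 10 fits without a single library, and also did not pass without collagen replicate 4 (0.0517), collagen replicate 5 (0.124), laminin replicate 2 (0.101), laminin replicate 3 (0.0912) or laminin replicate 5 (0.0581). Without the letter B libraries, Krt7 passed at -1.58 (adjusted p = 0.0357, range 0.0357 to 1.00), and Itga6 passed in the other direction at 0.44 (adjusted p = 0.0478, range 0.0478 to 1.00). Krt7, Itgb4 and Ddr1 overlap antisense or noncoding exons of Gm671, B230344G16Rik and Gm4577.

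Of the 36 gene lists tested, camera called 4, all lower in laminin. These were cytosolic ribosomal proteins (75 genes, adjusted p = 1.8e-09), cholesterol synthesis (25 genes, adjusted p = 8.2e-05), mitosis (58 genes, adjusted p = 7.5e-04) and hypoxia and glycolysis (46 genes, adjusted p = 0.0131). No call held with an estimated correlation, where the adjusted p was 0.738 for the ribosomal, cholesterol and mitosis lists and 0.743 for the hypoxia list, and fry, tested for change in one direction, called 0 of 36 lists at a lowest adjusted p of 0.199. Tested for change in either direction, fry called 6 lists, none of them among these 4: fatty acid oxidation and peroxisome (adjusted p = 1.6e-05), bile duct transport and secretion, chemokines and NF-kB targets, and fibrillar collagens and interstitial matrix (each 0.0010), fibroblast and stellate markers (0.0016) and the Notch pathway (0.026). In none of the 4 lists that camera called did a gene pass the test over all genes. Mean log2 differences were -0.23 for the ribosomal list, -0.26 for cholesterol synthesis, -0.10 for mitosis and -0.11 for hypoxia and glycolysis. Exact permutation tests of the list means per library gave p = 0.254, 0.206, 0.159 and 0.389 in that order, with adjusted p from 0.476 to 0.609. With the length and GC trend removed, the ribosomal mean was -0.092, with 13 of 75 genes above 0 in place of 0, and its call held (adjusted p = 6.0e-04, and 0.761 with an estimated correlation). In cholesterol synthesis, laminin replicate 1 stood at 0.71 above the mean of the 10 libraries on the log2 scale, against -0.17 to -0.61 in the other laminin libraries. Over that list alone, 0 of 25 genes were lower with all libraries or without any library but this one, and 19 of 25 were lower without it (camera adjusted p = 1.3e-16, range over the alternatives 1.3e-16 to 0.738). The ribosomal call was lost without the 2 collagen libraries of code letter D (adjusted p = 0.477, range over the alternatives 6.5e-17 to 0.738) and the mitosis call without the 3 of letter B (adjusted p = 0.565, range 1.2e-05 to 0.738), alternatives chosen after seeing the data. The hypoxia and glycolysis call was lost without collagen replicate 1 (adjusted p = 0.0635), laminin replicate 3 (0.376), laminin replicate 4 (0.254), letter D (0.0899) or letter B (0.236), and with the length and GC trend removed (0.0606), in a range of 4.9e-06 to 0.743.

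**Figure D2:**
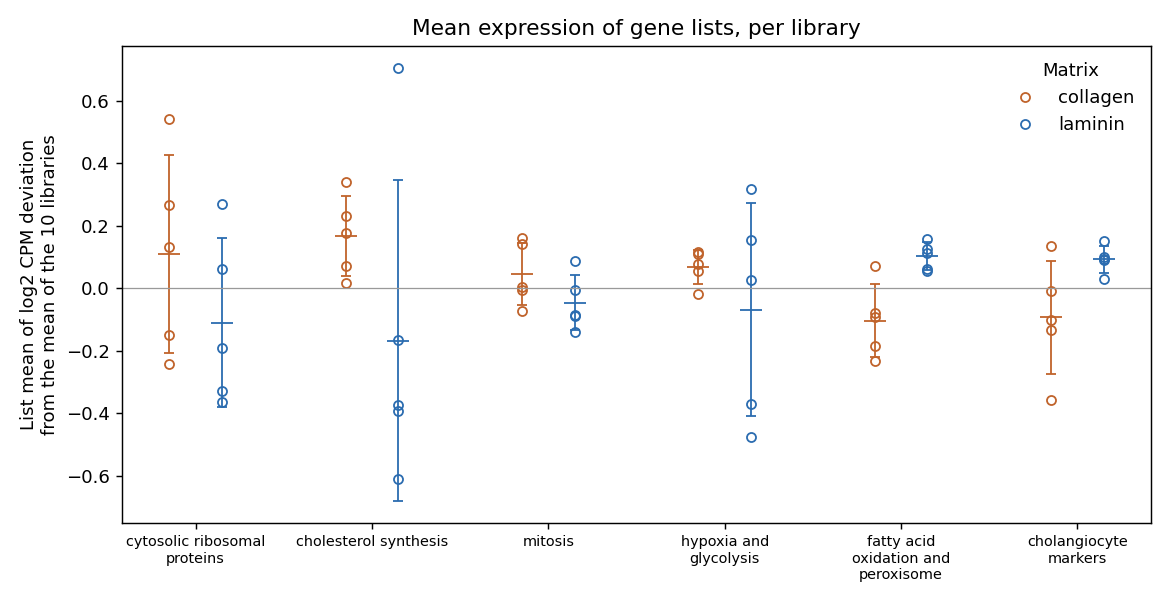
The y axis gives, for each library, the list mean of log2 CPM deviations from the mean of the 10 libraries, and the x axis 6 gene lists, with circles for libraries and bars for the mean and SD of 5 libraries per matrix. In the ribosomal list the collagen libraries span -0.24 to 0.54 and the laminin libraries -0.36 to 0.27.

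The other 32 lists did not pass in camera, with adjusted p from 0.0748 to 0.983. Within single lists, some genes passed when adjusted over the list alone, with no adjustment across lists, and the examples were chosen after their values were seen. In bile duct transport and secretion, 6 of 27 tested genes were higher adjusted over the list alone and 0 adjusted over all genes, among them the mucin Muc1 (32.2 ± 14.3 to 72.2 ± 16.9 CPM), the bile acid transporter Slc10a2 (log2 difference 1.21, SE 0.30) and the water channel Aqp1 (0.93, SE 0.29). That count was 0 without collagen replicate 3, laminin replicate 2 or laminin replicate 3, 2 without collagen replicate 1 and 3 without collagen replicate 5. The same 3 genes were the cholangiocyte markers higher over the list alone, of 19 tested, a count that was 0 without laminin replicate 2, 1 without laminin replicate 3 and 5 without collagen replicate 4. In fatty acid oxidation and peroxisome, 4 of 30 genes were higher over the list alone, Ppargc1a, Cpt1a and Hadhb among them, and 1 over all genes, with 3 to 5 over the list alone when single libraries were left out. In the Notch pathway 2 of 16 were higher over the list alone, Jag1 (0.73, SE 0.15) and Notch3 (1.16, SE 0.24), and the count was 2 without any single library. In fibrillar collagens and interstitial matrix, 3 of 18 were higher (Col5a3, Col6a3 and Tnc) and 1 was lower (Dcn) over the list alone. The higher count was 1 without collagen replicate 3, and 2 without collagen replicate 4, collagen replicate 5 or laminin replicate 3. Laminin replicate 4 stood apart in this list, at a list mean log2 deviation of 0.72 against -0.10 to 0.18 in the other laminin libraries. Tnc was at 235 CPM in it against 78.1 ± 11.5 CPM in the other laminin libraries (n = 4). Without it the log2 difference of Tnc was 0.54 in place of 1.05, and Tnc still passed in edgeR over the list alone (adjusted p = 0.0218). Tnc did not pass over the list alone without collagen replicate 3 (0.0585), 4 (0.0548) or 5 (0.0543).

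Among adhesion genes, 1 of 11 laminin receptors, Itga7, was higher over the list alone (log2 difference 1.15, SE 0.22), and the count was 1 without any single library. Of 7 other integrins, 1 was lower over the list alone, with 1 to 2 when single libraries were left out. Of 31 focal adhesion and contractility genes, 1 was higher and 2 were lower, with 0 to 1 and 0 to 3 when single libraries were left out. In chemokines and NF-kB targets, 2 of 27 were lower over the list alone, Vcam1 (-0.74, SE 0.14) and Il33 (-0.85, SE 0.19), a count that was 4 without collagen replicate 1 and 2 without any other library. Sod2 and Nfkbiz were higher over the list alone, a count of 2 that was kept without collagen replicate 4 and was 0 without collagen replicate 2, 3 or 5 or laminin replicate 2 or 3, and 1 without any other.

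Markers of cholangiocytes and of 5 other cell types were summed, and none of the 6 sums passed the two-sided exact permutation test after adjustment. The hepatocyte markers, of which 5 of 22 had a mean of 1 CPM or more, summed to 111 ± 18.8 CPM in collagen and 165 ± 22.7 CPM in laminin (exact permutation p = 0.0159, adjusted 0.0952, n = 5 per group), led by Hnf4a and Alb. The 3 hepatocyte markers tested singly, Alb, Ttr and Hnf4a, were higher over the list alone and 0 passed over all genes. That count was 0 without laminin replicate 2 or 3 and 1 without laminin replicate 4 or 5. The sums were 723 ± 66.4 and 753 ± 71.2 CPM for fibroblast and stellate markers, led by Fbln2 and Fbln1 (exact permutation p = 0.468, adjusted 0.937, n = 5). Endothelial marker sums were 20.5 ± 4.42 and 18.1 ± 3.12 CPM (exact permutation p = 0.325, adjusted 0.937, n = 5), and leukocyte sums 69.8 ± 16.9 and 72.3 ± 15.5 CPM (exact permutation p = 0.802, adjusted 1, n = 5). Red cell markers summed to 0 CPM in collagen and 0.0461 ± 0.103 CPM in laminin (exact permutation p = 1, adjusted 1, n = 5). Cholangiocyte markers summed to 6838 ± 825 and 6734 ± 715 CPM (exact permutation p = 0.841, adjusted 1, n = 5).

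The libraries differed in how expression depended on transcript length. The main axis of variation held 47.3% of the variance. Its gene loadings correlated with log2 transcript length at a Spearman rho of 0.72, and with GC content at -0.50, across genes, which are not independent replicates. The slope per doubling of length was -0.058 ± 0.230 in collagen and 0.058 ± 0.117 in laminin, log2 units (exact permutation p = 0.357, adjusted 0.714, n = 5 per group). Within collagen, the slope was 0.178 and 0.149 in replicates 1 and 2, and -0.061, -0.367 and -0.187 in replicates 3, 4 and 5. Replicate 3 thus had the sign of replicates 4 and 5. There, the letter of the library code, whose meaning is not stated, divided libraries 1 to 3 (letter B) from 4 and 5 (letter D). Between them 1708 genes differed in edgeR, 585 higher in D with a median transcript length of 1520 nt and 1123 lower with a median of 5741 nt. That count was 0 without collagen replicate 1, 2 or 4 (2545, 2953 and 1297 at an unadjusted p under 0.05), 3655 without collagen replicate 3, 635 without collagen replicate 5 and 358 without laminin replicate 2. Without collagen replicate 4 or 5, letter D was a single library, assumed to vary like the other groups. Within laminin, letter F minus letter E gave 0 genes in edgeR, with 414 at an unadjusted p under 0.05 and 1 gene called by DESeq2. Without laminin replicate 5, edgeR called 26 genes, but letter F was then laminin replicate 4 alone, assumed to vary like the other groups, so the count describes that library. Each letter occurs in a single matrix, so a batch by letter and the matrix cannot be told apart.

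**Figure D3:**
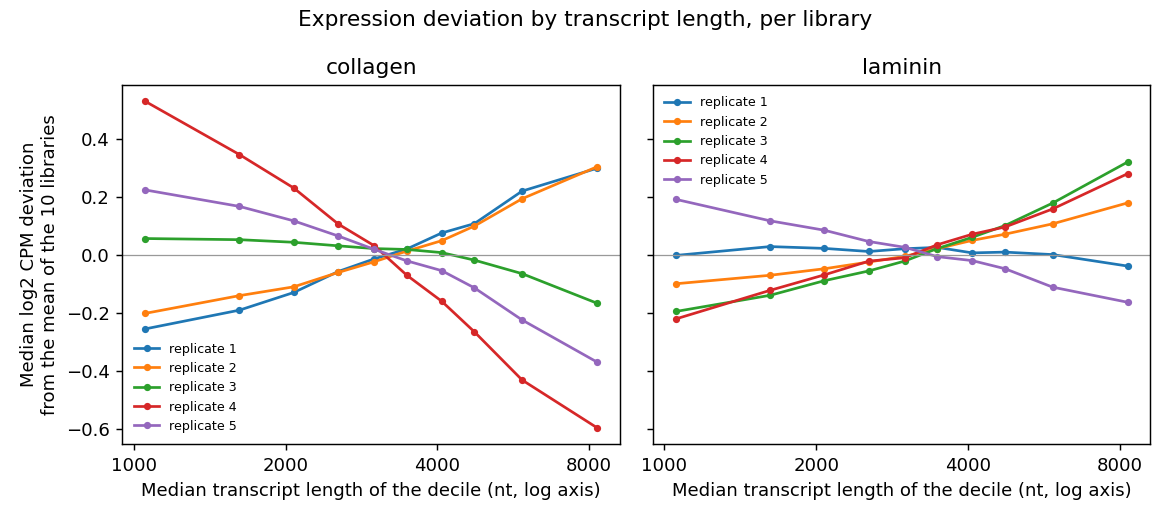
The x axis gives the median transcript length of 10 equal groups of genes (nt, log axis) and the y axis the median log2 CPM deviation from the mean of the 10 libraries, with a line for each library. Collagen replicate 4 ran from 0.53 in the shortest group to -0.60 in the longest, and collagen replicate 1 from -0.26 to 0.30.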

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

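Tests on the length dependence of the main axis and on the code letter were chosen after the result was seen, those on laminin replicate 4 before, and the thinning test of depth after a correlation with total count had been seen, with its bounds set before it was run. In 138 groups of 5 libraries, 5 held a value far from the other 4, where chance gives about 5%, or 6.9. Laminin replicate 4 gave 3 of them: Boc at 3.02 log2 CPM against 2.16 in the next library, the mesenchymal transition list at a mean log2 deviation of 0.272 against -0.102, and epithelial junctions at -0.0727 against 0.0960. In collagen replicate 1 the heat shock protein list stood at -0.149, against 0.00297 in the next library. In laminin replicate 1 the fatty acid synthesis list stood at 0.319, against -0.00910.

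Laminin replicate 4 also had 30 genes at least 2-fold above, and 5 at least 2-fold below, every other library, with Tnc at 235 CPM and Fgfr2 at 115 CPM. With the length and GC trend removed, 80% of the 35 genes still stood apart, so the fitted trend did not account for most of them. This was likely beforehand. The median log2 deviation of this library ran only from -0.22 in the shortest transcripts to 0.28 in the longest, against a margin of 2-fold. For fibroblast-type cells, the summed CPM of 7 fibroblast genes was 55.4 against an excess of 1570 CPM in Fn1 and Tnc. This met the bound set beforehand against such cells. Much of that excess was Fn1, at 2790 CPM against 1496 ± 232 CPM in the other laminin libraries, and Fn1 was not among the 35 genes. Tnc was at 235 CPM against 78.1 ± 11.5 CPM. The test therefore does not decide whether such cells account for the 35 genes. A mislabelled sample and mixtures, fibroblast-type cells included, stay open. No other biological explanation was tested, as the labels name no difference among laminin cultures but the code letter. Its meaning is not stated, and laminin replicates 4 and 5 share letter F. Collagen replicate 4 had 56 genes at least 2-fold below every other library.

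The main axis of variation followed transcript length and, less strongly, GC content. Loadings of 9820 genes outside the fixed lists gave a Spearman rho of 0.714 with log2 length. That repeats the observation on largely the same genes and does not bear on whether read recovery was the cause. The number of reads itself was argued against: with every library thinned to 4424725 counts the axis scores correlated with the original scores at an absolute r of 1.00. Thinning cannot test a cause that changes both total count and length dependence. Total count and score gave Pearson's r = 0.284 (permutation p = 0.425) and Spearman's rho = 0.406 (permutation p = 0.246) over 10 libraries, with r = 0.435 without the 2 farthest totals, a test that excludes nothing at this number and was replaced by the thinning. The code letter cannot be told apart from chance differences in collagen, where D and B separated at an exact permutation p of 0.1, the smallest that 10 assignments allow, while in laminin the letters overlapped. What set the length dependence, such as read recovery, RNA integrity or a biological difference between cultures, stays open.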

How the results depend on the processing

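The length and GC correction, its lists and leaving out letters were chosen after seeing the data. The cause of the shifts below was not tested. Against 16 genes, the count was 209 with DESeq2, 29 without a filter, 99 with a mean per code letter, 463 with 1 surrogate variable, 122 with the length and GC offset, 5 without letter D and 2083 without letter B libraries. In edgeR it was 0 against a fold of 1.5 (126 at an unadjusted p under 0.05) and 0 with the replicate number as a block (1049). Same-number deviations correlated at -0.31, 0.26, -0.11, -0.33 and 0.48, and 1 of 10 libraries matched its own number best. Within groups 1 axis held 52.8% of the variance, so pairing stays open. Leaving out 1 library gave 0 (collagen 3 or 5, laminin 2) to 64 (laminin 1) genes. Between were 2 (collagen 2), 5 (laminin 3 or 5) and 36 (laminin 4). The 16 genes kept their direction in all 368 values and passed in 215.

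Of 100 library splits drawn from 126, the real one included, 2 gave at least 16 genes. With the offset 2 reached 122, and with the surrogate variable 3 reached 463. This excludes chance at 5% only if libraries sharing a letter are independent, which is unknown. The highest other splits gave 3124, 366 and 2893 genes, all for collagen 1 and 2 with laminin 2, 3 and 4 against the rest. That split follows the main axis score's sign and points to a larger structure than the matrix. With the trend removed, the called genes kept a median of 0.902 of their log2 fold change, and 14 of 16 stayed called. This was likely for genes chosen by clear changes and does not test the trend as a cause.

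List calls numbered 4 to 8 without single libraries (8 without collagen 4 or laminin 4, 7 without laminin 2). They were 0 with an estimated correlation, and with fry 0 in 1 direction and 6 in either. With the trend removed, camera called 6 lists, 2 higher and 4 lower. D minus B gave 217 genes with the offset, 0 against a fold of 1.5 (718 at an unadjusted p under 0.05) and 0 to 3655 when single libraries were left out (0 without collagen 1, 2 or 4, 3655 without collagen 3, 635 without collagen 5, 358 without laminin 2). F minus E gave 1 gene with DESeq2, and 0 to 26 when single libraries were left out (26 without laminin 5, which leaves laminin 4 alone in letter F). Arms of 1 library (D without collagen 4 or 5, F without laminin 4 or 5) were assumed to vary like the other groups, and their counts describe that library, not the letter.

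None of the genes that changed sign had passed. Itgb1 went to -0.00019 with DESeq2, -0.00012 with its size factors, -0.0058 by library size, -0.013 unfiltered, -0.0078 with the CPM filter, -0.012 with the surrogate variable, -0.067 without letter D, and to between -0.033 and -0.012 without collagen 4 or 5 or laminin 1 or 2, where the highest value without a single library was 0.032 (laminin 4) and that without letter B 0.11. Krt19 went to 0.039 without collagen 4 (-0.27 without laminin 1), 0.056 with the surrogate variable and 0.19 without letter D. Itgb4 went to -0.014 without collagen 2 (0.10 without laminin 4), -0.20 with the offset and -0.13 without letter B. Lama5 went to -0.11 with the offset, Sox9 to -0.062 without laminin 4 (0.22 without laminin 1) and Itga6 to 0.44 without letter B (adjusted p = 0.0478). The oxidative phosphorylation list turned lower in laminin without letter B (adjusted p = 5.9e-05), with letter means (0.901) and without collagen 1 (0.621), collagen 2 (0.895) or laminin 5 (0.770), and was higher at 2.8e-06 without collagen 4 and 0.0197 without laminin 4. Depth limited genes near 3 counts. Simulated 1.5-fold changes were recovered at 71.6% by edgeR without library trends, at 23.9% with them and at 56.7% with them and the offset.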

Other observations

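The tests with the length and GC trend removed or with code letters left out, and those on matched lists, were chosen after the result was seen, while the uncorrected edgeR and camera tests were set beforehand. Of the 122 genes called in edgeR with the length and GC trend removed, some are given as single genes picked after their values were seen, and they stand for no tested group. Ppargc1a, a transcriptional coactivator, was higher in laminin (log2 difference 1.30, SE 0.18), as was Mdh2, a malate dehydrogenase (0.40, SE 0.06), and both passed without any 1 of the 10 libraries. Esrra (0.54, SE 0.11), Idh3a (0.52, SE 0.10), Ogdh (0.35, SE 0.07) and Cpt1a (0.50, SE 0.11) were called with all libraries. Without single libraries they passed in 2, 3, 4 and 3 of 10 fits, with highest adjusted p of 0.130, 0.0982, 0.0935 and 0.125. All 4 lost their calls without collagen replicate 1, 2, 3 or 5, or laminin replicate 2 or 3, as did all but Ogdh without laminin replicate 5 and Esrra without collagen replicate 4. Without the correction the adjusted p of these 6 genes ran from 0.0807 for Ppargc1a to 0.445 for Mdh2.

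With the trend removed, camera called 6 of the 36 lists. Higher in laminin were oxidative phosphorylation and fatty acid oxidation and peroxisome, and lower were the ribosomal, cholesterol synthesis and mitosis lists and focal adhesion and contractility (adjusted p = 0.0276, and 0.538 with an estimated correlation). Only fatty acid oxidation and peroxisome held with an estimated correlation, and fry in one direction called it, oxidative phosphorylation and cholangiocyte markers (adjusted p = 0.0276). In the fatty acid oxidation and peroxisome list, fixed beforehand, 5 of 30 genes were called higher with the trend removed. Camera on the corrected values gave adjusted p = 2.1e-04 (adjusted p = 0.0394 with an estimated correlation). The permutation test of the list mean per library gave an exact p of 0.00794, the smallest possible, as it did for focal adhesion and contractility. Adjusted over the 36 lists it was 0.114, which decides nothing, since with 252 assignments 1 list alone could not pass. Fry in one direction gave adjusted p = 2.5e-04 on the corrected values and 0.293 uncorrected. Uncorrected, camera gave adjusted p = 0.0748 (0.738 with an estimated correlation), so its calls in one direction rest on the correction.

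A hypothesis is that mRNA of nuclear oxidative phosphorylation genes is higher in laminin once length and GC content are accounted for. With the trend removed the list mean was 0.19 higher on the log2 scale, with an exact permutation p of 0.0159 (n = 5 per group) that was 0.114 when adjusted over the lists, where 1 list alone could not pass, and 4 of 5 laminin libraries lay above the highest collagen library. Its percentile among 10000 lists matched on length, GC content and expression was 100, and that of the ribosomal list was 0. The matched lists were drawn gene by gene, so the percentile ignores correlation between genes. It therefore does not measure the spread between libraries and gives no support for a matrix difference. Camera gave adjusted p = 2.1e-14 with the preset correlation and 0.322 with an estimated correlation, and fry in one direction 0.0276, so the list result is open. As a check on a residual trend of short transcripts, cytosolic ribosomal proteins, of similar median length (937 against 918 nt), had a mean log2 difference of -0.0901. In edgeR the correction raised both list means, from -0.229 to -0.0918 for the ribosomal list and from 0.0386 to 0.190 for oxidative phosphorylation. The ribosomal list began lower, so its sign cannot exclude such a trend. Uncorrected, the list was higher without letter D (adjusted p = 2.1e-12) and lower without letter B (5.9e-05), so it depends on which collagen libraries are used and may follow the correction.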
